A study of Gallus gallus with 2 samples.

How the data were processed

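Total RNA of 2 DT40 cultures, 1 H2A.Z-1 KO and 1 H2A.Z-2 KO, was labelled with biotin and hybridised to an Affymetrix chicken expression array, per the labels' protocols. The deposited values are linear signal intensities of probe sets, made with MAS5 per the submitters' processing notes. MAS5 reports 1 background-corrected signal per probe set and scales each array to a common target. Its version, scaling and detection settings are not given in the sources used here. The deposited intensity values run from under 1 to 50243 and have the same 2% trimmed mean of about 500 on both arrays, so they were taken as scaled and linear, from the values. Such scaling assumes a similar total signal on both arrays and would hide a global difference in RNA per cell. Scanner files, detection calls and a wild-type array were not used here.

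The 96 control probe sets of the manufacturer were left out of all counts. A floor was set at the 60th percentile of the other 38439 probe sets over both arrays, a signal of 98.2. Signals under it were set to it, because MAS5 signals near background have no reliable order. A fold difference against a probe set under the floor is given as "at least". Log2 ratios are H2A.Z-1 KO minus H2A.Z-2 KO, and the threshold was 2-fold. The value of a gene is the mean log2 ratio of its probe sets above the floor. Where only some of several probe sets were under the floor, the fold is also given as "at least". The bound covers only the probe sets above this floor, and a lower floor can admit dimmer probe sets that lower the mean of the gene. Signals of such genes are geometric means after the floor. Gene names came from a table of the array's platform annotation: 27178 probe sets had 1 gene symbol, 177 had several and 11180 were unnamed. Symbols were updated by gene identifier for 26863 probe sets with a RefSeq gene table of assembly GRCg7b, which also gave chromosome and gene order. The genome build of the array design is not given in the sources used here, so no coordinates are printed.

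Technical quality was described from the arrays themselves. The 63 spiked-in control probe sets above the floor had a mean log2 ratio of 0.04 with an SD of 0.19, and none differed 2-fold. Signal ratios of 3' to 5' probe sets were 1.24 and 1.21 for actin, 1.02 and 1.05 for GAPDH and 1.20 and 1.27 for EF1A on the H2A.Z-1 KO and H2A.Z-2 KO arrays. These are very bright transcripts. Of 3588 genes with at least 2 probe sets above the floor, 1291 had probe sets of opposite sign, and the pooled SD between probe sets of 1 gene was 0.36 on the log2 scale. Of 624 probe sets that passed 2-fold in such genes, the mean of the gene's other probe sets had the same direction in 95.8% and also passed 2-fold in 54.0%. This spread measures probe differences within 2 arrays and not differences between cultures.

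The genes named in the text followed a rule fixed before the data were examined: the knocked-out genes, the 12 genes per direction with the largest ratio and consistent probe sets, the 8 per direction with at least 2 probe sets all past 2-fold, 2 members per direction of each list described, and all members of the H2A.Z deposition list. Genes with only a locus, open reading frame or clone name were left out of these rankings by ratio. Other genes named in the report are marked as chosen after their values were seen, and the further genes in the closing section were also chosen in that way. The 30 gene lists were written from general knowledge before the data were examined. A list's median was ranked among 10000 random lists drawn without replacement from 20 brightness bins. A list had to have at least 5 measured genes. That minimum was chosen after a first look at the list values. At the same point, matching of list members through synonyms was dropped because it placed several genes on related genes, and it was kept as an added alternative. The 5 lists added later were chosen after seeing the data.

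Alternatives fixed in advance were median centring, quantile normalization, removal of the brightness trend by lowess (fraction 0.3, 3 iterations), floors at the 40th and 80th percentiles, no floor with a pseudocount of 1, thresholds of 3-fold and 1.5-fold, exclusion of probe sets whose suffix marks possible matches to several transcripts, the brightest probe set per gene, and list means. The steps were tested on simulated data for the H2A.Z-1 KO against H2A.Z-2 KO comparison, with 16501 probe sets above the floor. Of 100 probe sets changed by 1.5 on the log2 scale 91 passed 2-fold, and of 100 changed by 3 all 100 did. All were drawn from probe sets with a mean signal above 2 times the floor, so recovery of dimmer ones was not tested. The simulated noise was normal, with the scaled median absolute deviation of the real ratios in each brightness bin. That width includes some real differences but gives little weight to the tails of the real ratios. With it 390 unchanged probe sets passed 2-fold, which is no upper bound on false calls in the real arrays. A list of 40 genes raised by 0.3 reached percentile 100, a list left alone stood at 3.90, and 11 of 200 random lists without a change lay outside the central 95%. The last number checks only the ranking step, because random lists were ranked among random lists. The tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for quantile normalization.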

Results

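Gene expression was measured in DT40, a chicken B-cell line from a bursal lymphoma that is widely used for gene targeting. One array was hybridised with RNA of cells lacking the histone variant H2A.Z-1, and 1 array with RNA of cells lacking the sister variant H2A.Z-2. H2A.Z replaces H2A in a fraction of nucleosomes, and vertebrates encode these 2 closely similar forms in separate genes. The H2A.Z-2 gene was disrupted permanently, whereas the H2A.Z-1 KO cells carried a tetracycline-repressible H2A.Z-1 transgene in place of a permanent loss. Both cultures received tetracycline at 2 µg/ml for 72 hours. No wild-type array was analysed here. Each value below therefore contrasts the 2 knockouts with each other, and neither direction can be assigned to a gain in one line or a loss in the other. With 1 array per genotype there is no replicate error, no test and no p-value, and the number of arrays limits the precision. Both arrays held 38535 probe sets with 2% trimmed mean signals of 500.2 and 500.1. Log2 signals of the 14050 probe sets above the floor of 98.2 on both arrays correlated across probe sets with r = 0.959; probe sets are not independent replicates.

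The first question was whether each array lacked the transcript its label names. H2AFZ, the gene of H2A.Z-1 on chromosome 4, had a signal of 614.6 on the H2A.Z-1 KO array and 27642 on the H2A.Z-2 KO array. The signal in the H2A.Z-1 KO cells was thus 45.0-fold lower, at 2.22% of the other array. H2AZ2, on chromosome 22, gave 20911 on the H2A.Z-1 KO array and 42.1, under the floor, on the H2A.Z-2 KO array, a difference of at least 213-fold. Both differences had the direction that the labels call for. One probe set reported each gene, that of H2AFZ being of a kind that can match several transcripts. Whether these probes lie in the deleted parts or detect the transgene was not analysed here. The remaining H2AFZ signal can therefore not be assigned to the transgene or to background.

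The second question was how far the transcriptomes of the 2 knockouts differed. Of 16701 probe sets above the floor on at least 1 array, 539 were at least 2-fold higher on the H2A.Z-1 KO array and 658 on the H2A.Z-2 KO array. Among 7977 named genes the numbers were 229 and 303. For 55 and 59 genes, respectively, at least 2 probe sets were measured and every one of them passed 2-fold in the same direction. Which array had more calls depended on the processing. The share of 2-fold probe sets that were higher on the H2A.Z-1 KO array was 45.0% as deposited, 54.8% after removal of the brightness trend, 33.6% with the floor at the 40th percentile and 58.6% with the floor at the 80th. Without a floor the counts were 4080 and 7338 probe sets.

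**Figure D1:**
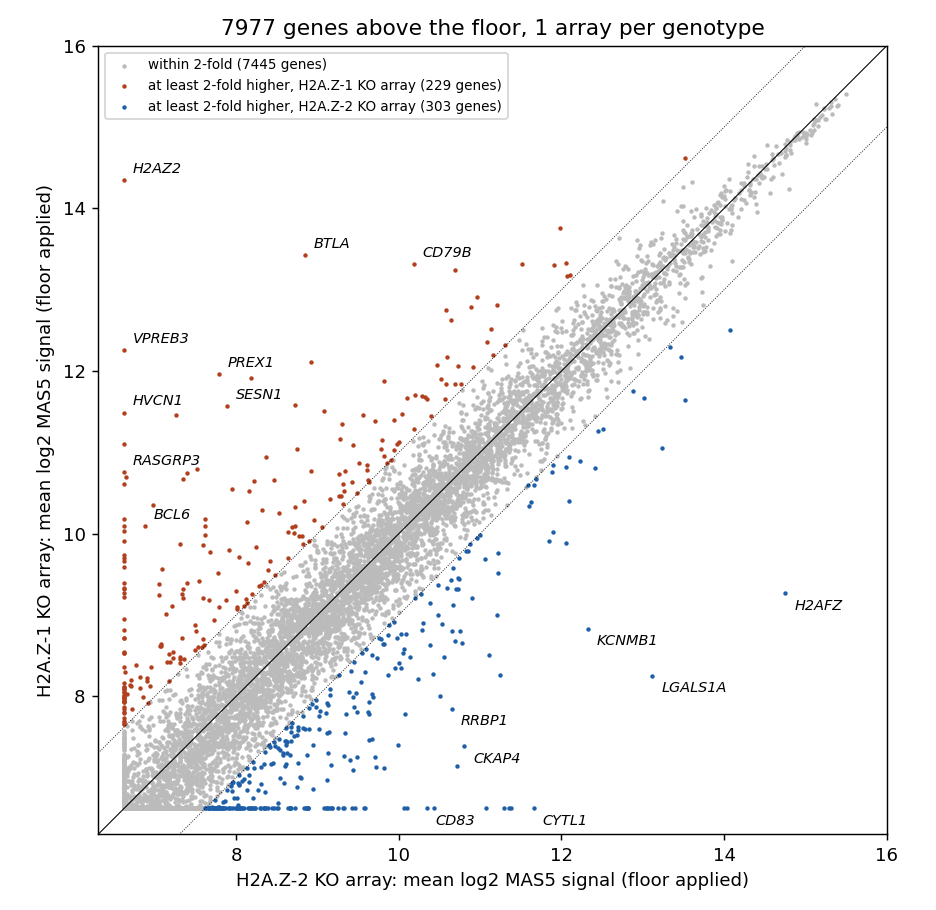
Mean log2 MAS5 signal of each of 7977 genes on the H2A.Z-2 KO array (x axis) and the H2A.Z-1 KO array (y axis), 1 point per gene and 1 array per genotype. The solid line marks equal signal, the dotted lines 2-fold differences, and points along the edges lie at the floor. H2AZ2 and H2AFZ lie far from the line in opposite directions, and 229 and 303 genes lie beyond the dotted lines.

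Of the genes named by the rule and higher on the H2A.Z-1 KO array, VPREB3 had the largest ratio after H2AZ2. VPREB3, which associates with the pre-B cell receptor, was at least 49.8-fold higher (signal 4893 against a value under the floor). HVCN1, a voltage-gated proton channel of B cells, was at least 29.3-fold higher over 2 probe sets. BTLA, an inhibitory receptor of lymphocytes, had signals of 11026 and 457.7, a difference of 24.1-fold. This rests on 1 probe set of a kind that can match several transcripts. RASGRP3, a Ras exchange factor downstream of the B-cell receptor, was at least 17.6-fold higher, and the lipid-presenting molecule CD1C at least 15.9-fold. BCL6, a transcriptional repressor of germinal centre B cells, was at least 9.31-fold higher. PREX1, an exchange factor for Rac, was 18.1-fold higher, a log2 ratio of 4.18 that fell to 2.49 with the floor at the 40th percentile. SESN1, a stress-responsive sestrin, was 12.8-fold higher. DACT2, a modulator of Wnt signalling, was at least 10.3-fold higher. SFRP1, a secreted Wnt antagonist, was 10.3-fold higher over 2 probe sets, but its log2 ratio of 3.36 fell to 1.44 with the floor at the 40th percentile and to 0.93, under 2-fold, with no floor. VAT1 was at least 22.3-fold higher on its 1 probe set above the floor, but its log2 ratio of 4.48 fell to 3.01 with the floor at the 40th percentile and to 3.07 with no floor. PPP1R14C was at least 16.6-fold higher, FAM110D 18.4-fold and PPP1R19L 13.3-fold.

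Of the genes named by the rule and higher on the H2A.Z-2 KO array, CYTL1 and LGALS1A followed H2AFZ. The secreted protein CYTL1 was at least 32.9-fold higher. The galectin LGALS1A was 29.1-fold higher, with signals of 8876 against 305.1. Like CD83 and CD200R1A below, LGALS1A had 1 probe set, of a kind that can match several transcripts. The integrin subunit gene ITGA4 was at least 14.1-fold higher, the cadherin CDH11 at least 5.91-fold, the actin-bundling plastin PLS3 at least 7.81-fold and the actin-associated PALLD 11.9-fold, its log2 ratio of -3.58 falling to -2.18 with no floor. CKAP4 and RRBP1 encode membrane proteins of the rough endoplasmic reticulum. CKAP4 was at least 10.7-fold higher, and RRBP1 had a log2 ratio of -2.81, or -0.96, under 2-fold, with no floor. CD83, a marker of activated lymphocytes and dendritic cells, was at least 13.2-fold higher, the receptor gene CD200R1A at least 21.9-fold and the proton-sensing receptor GPR65 at least 5.66-fold, with a log2 ratio of -2.50 that fell to -1.36 without probe sets that can match several transcripts. KCNMB1, a potassium channel subunit, was 11.2-fold higher and AHR1A, an aryl hydrocarbon receptor, at least 11.2-fold, with a log2 ratio of -3.48, or -2.16 without such probe sets. SLC25A21, a mitochondrial carrier, was at least 26.7-fold higher. MLIP was at least 25.6-fold higher on 1 probe set of a kind that can match several transcripts, and without such probe sets its log2 ratio was -0.45, under 2-fold. MLLT6 was at least 27.1-fold higher on its 1 probe set above the floor, but its log2 ratio of -4.76 fell to -2.58 with no floor. KLF13 and BEND7 were at least 5.46-fold and 6.97-fold higher. These 34 leading genes, H2AFZ and H2AZ2 included, kept their direction under every alternative that measured them.

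Gene lists fixed before the data were examined were each described by the median log2 ratio of their measured members, H2A.Z-1 KO minus H2A.Z-2 KO. This median was placed among 10000 random lists of the same size and brightness, which describes these 2 arrays and is no test of genotype. Of 29 lists with at least 5 measured genes, 11 lay outside the central 95% of random lists, where 1.45 would if genes varied independently. Genes of 1 list that vary together widen the spread of its median, so the comparison with 1.45 can overstate the excess. Some lists also share members, such as APEX1 and UNG in the DNA repair and the immunoglobulin diversification lists. The lists are therefore not independent of each other. Of the 11, 8 were higher on the H2A.Z-1 KO array and 3 on the H2A.Z-2 KO array.

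**Figure D2:**
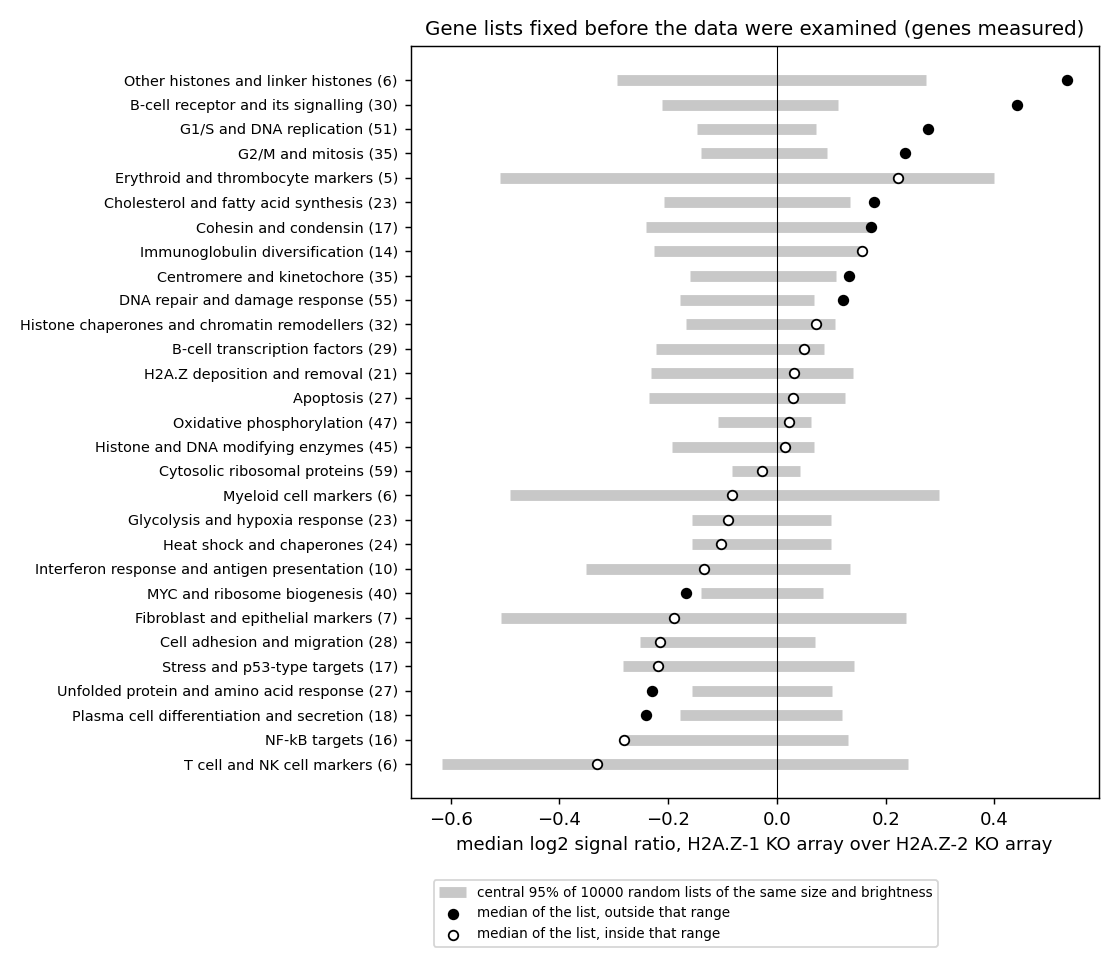
Median log2 signal ratio (H2A.Z-1 KO over H2A.Z-2 KO array, x axis) of each of 29 gene lists, with the number of measured genes in parentheses. Grey bars span the central 95% of the medians of 10000 random lists matched in size and brightness, and filled points are the 11 medians outside it. The B-cell receptor list stands at 0.44 and the secretion list at -0.24.

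The B-cell receptor and its signalling genes formed the most displaced of the large lists. Of 30 measured genes, 8 were at least 2-fold higher on the H2A.Z-1 KO array, 2 on the H2A.Z-2 KO array and 20 within 2-fold, with a median log2 ratio of 0.44, above 100% of random lists. CD79B, a signalling chain of the receptor, was 8.76-fold higher in H2A.Z-1 KO cells, with signals of 10163 and 1160, in addition to RASGRP3. Chosen after their values were seen, the adaptor gene PIK3AP1 was 7.24-fold higher, the co-receptor gene CD72 4.19-fold, CD74 3.73-fold and the kinase gene BTK 2.61-fold. In the opposite direction, the Src-family kinase gene FYN was 3.24-fold and TNFRSF13B, a receptor for B-cell survival factors, 2.59-fold higher on the H2A.Z-2 KO array. Single probe sets reported CD79B, PIK3AP1, BTK and TNFRSF13B.

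The 29 measured B-cell transcription factors went both ways, with 6 at least 2-fold higher on the H2A.Z-1 KO array and 5 on the H2A.Z-2 KO array. Their median of 0.05 lay at percentile 93.9 of random lists, inside the central 95%. It passed that range under 4 alternatives, the highest percentile being 99.9, and turned to -0.12 with the brightest probe set per gene (percentile 22.0) and without probe sets that can match several transcripts (37.7). FOXO1 was 10.0-fold higher and BCL6 at least 9.31-fold higher in H2A.Z-1 KO cells. FOXO3 was at least 7.77-fold and ID2, an inhibitor of E-proteins, at least 5.04-fold higher in H2A.Z-2 KO cells. Chosen after their values were seen, IKZF3 was 5.97-fold and EBF1 at least 4.29-fold higher in H2A.Z-1 KO cells, whereas the E-protein gene TCF3 was 4.41-fold higher in H2A.Z-2 KO cells. The probe sets of ID2 spanned log2 ratios from -3.67 to -0.28.

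**Figure D3:**
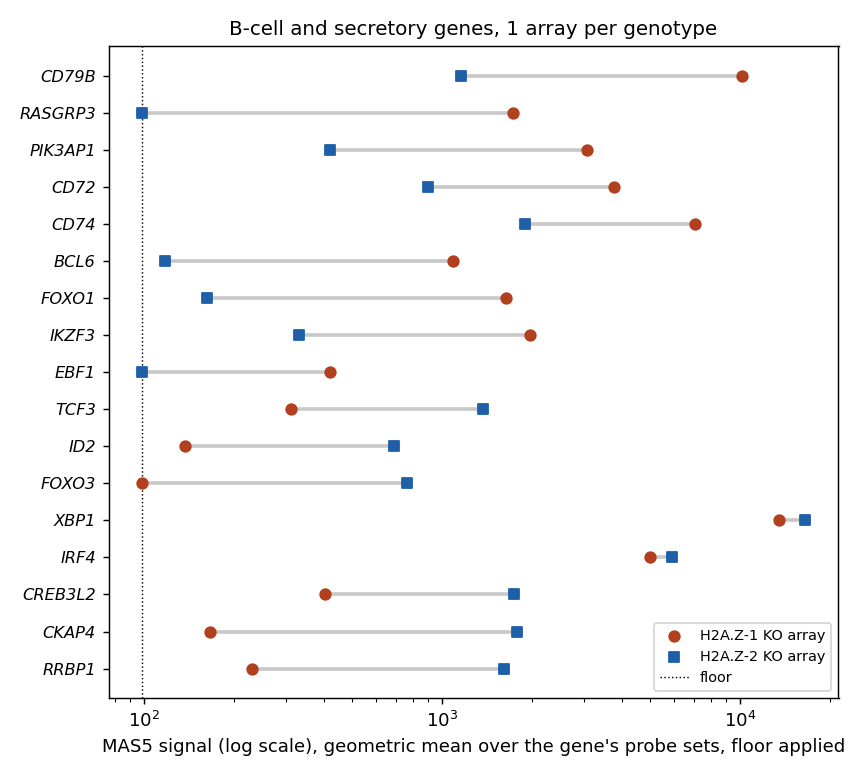
MAS5 signal on a log axis (x axis) of 17 B-cell and secretory genes named in the text on the H2A.Z-1 KO array (circles) and the H2A.Z-2 KO array (squares), as the geometric mean over the probe sets of each gene, 1 array per genotype. The dotted line is the floor of 98.2. CD79B lies at 10163 and 1160, whereas XBP1 and IRF4 lie close together on both arrays. The genes drawn are a selection, some of them chosen after their values were seen, and do not show the balance of directions in their lists. The text also names FYN and TNFRSF13B, which were higher on the H2A.Z-2 KO array, and SEC61B, SRP54 and JCHAIN, which differed little.

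Cell division genes shifted as a group by a small amount. The G1/S and DNA replication list, with 51 measured genes, had a median of 0.28, and the G2/M and mitosis list, with 35, a median of 0.24, each at percentile 100 of random lists. Most members, 48 of the 51 and all 35, stayed within 2-fold. In the first list CDK6 was at least 3.09-fold and RFC5, a clamp-loader subunit, 2.42-fold higher on the H2A.Z-1 KO array, and the cyclin gene CCND3 was 2.34-fold higher on the H2A.Z-2 KO array, followed by ORC3 at -0.68. In the second none passed 2-fold, the mitotic genes NUSAP1 and TOP2A having log2 ratios of 0.75 and 0.68 and CEP55 and CCNA2 -0.30 and -0.26. The list of DNA repair genes (55 measured) had a median of 0.12, with RAD54B 2.57-fold and the uracil glycosylase gene UNG 2.60-fold higher on the H2A.Z-1 KO array, APEX1 2.04-fold higher on the H2A.Z-2 KO array and NBN at -0.98. Centromere genes (35) stood at 0.13, cohesin and condensin genes (17) at 0.17 and cholesterol and fatty acid synthesis genes (23) at 0.18, with no member past 2-fold. Their most distant members were OIP5 (0.78), SGO1 (0.77), ZWILCH (-0.46) and CENPL (-0.45), then PDS5B (0.80), SMC3 (0.60), SMC6 (-0.18) and STAG1 (-0.09), and INSIG2 (0.86), INSIG1 (0.62), ACSS2 (-0.78) and SQLE (-0.47). The repair, centromere, cohesin and cholesterol lists fell inside the central 95% when the mean replaced the median, at percentiles 94.9, 94.5, 96.0 and 90.2. The cohesin list was also inside with quantile normalization (97.0), with the brightness trend removed (97.4) and with the floor at the 40th percentile (96.6), the cholesterol list with that floor (94.9), and the centromere list without probe sets that can match several transcripts (94.1). The 6 measured genes of the list of other histones had a median of 0.53, but 2 of the 3 most displaced do not encode histones: the histone mRNA-binding SLBP (0.92) and, chosen after its value was seen, the chaperone NASP (0.60). The macro-histone gene H2AFY2 was 2.62-fold higher, and H3F3B stood lowest at -0.03. This list fell to percentile 95.9 without the probe sets that can match several transcripts.

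The secretion, unfolded protein, and MYC and ribosome biogenesis lists lay on the other side. The list of plasma cell differentiation and secretion, with 18 measured genes, had a median of -0.24, at percentile 0.19. One member passed 2-fold, CREB3L2, a transcription factor that activates secretory pathway genes, which was at least 4.32-fold higher on the H2A.Z-2 KO array. ELL2 stood at -0.75, SEC61B at 0.13 and SRP54 at 0.04. The unfolded protein and amino acid response list (27 genes) had a median of -0.23, at percentile 0.12, with no member past 2-fold, CHAC1 at -0.93, SLC1A4 at -0.80, SLC38A2 at 0.70 and ASNS at 0.35. The list of MYC and ribosome biogenesis genes (40) had a median of -0.17, at percentile 0.76, with only UBTF past 2-fold (2.40-fold), MYC at -0.57, CAD at 0.35 and RRP12 at 0.31. Chosen after their values were seen, the plasma cell regulators XBP1 and IRF4 had log2 ratios of -0.30 and -0.25, and the joining chain gene JCHAIN 0.00. Without probe sets that can match several transcripts the secretion list moved to percentile 6.23 and the MYC list to 4.29, both inside the central 95%. The MYC list was also inside it with the brightest probe set per gene (9.23) and with the mean (3.17).

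The remaining 18 lists lay inside the central 95%. Nearest to its limit were NF-kB targets (16 genes, median -0.28, percentile 2.61), which passed it under 6 alternatives, and immunoglobulin diversification (14 genes, 0.16, percentile 97.4), which passed it under 5 and whose list mean was -0.02. Cell adhesion (-0.22), stress and p53-type targets (-0.22), interferon response (-0.13), heat shock (-0.10) and glycolysis (-0.09) had negative medians. With the floor at the 80th percentile the adhesion list (-0.52, percentile 0) and the stress list (-0.40, percentile 0.235) left the central 95%, and the means of the stress and interferon lists were positive (0.01 and 0.07). Ribosomal proteins (-0.03), histone and DNA modifying enzymes (0.01), oxidative phosphorylation (0.02), apoptosis (0.03) and chromatin remodellers (0.07) stood near 0. All of these but apoptosis changed sign under at least 1 alternative, and the remodellers left the central 95% with the brightest probe set per gene (0.13, percentile 98.2). Marker lists of other cell types had few measured genes and also lay inside: T and NK cells (6 genes, -0.33), fibroblasts and epithelium (7 genes, -0.19), myeloid cells (6 genes, -0.08) and erythroid cells and thrombocytes (5 genes, 0.22). Without probe sets that can match several transcripts the myeloid list (-0.46, percentile 2.49) and the erythroid list (percentile 98.4) left it, and both lists changed sign under other alternatives. Of the early B-lineage list only VPREB3 and GATA2 were measured.

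A further question was whether the 2 knockouts differed in transcript levels of the proteins that deposit or remove H2A.Z. A change shared by both knockouts would not show in this ratio. Of 31 genes listed 21 were measured, so the list does not cover all of this machinery. None of the 21 passed 2-fold, and their median of 0.03 lay at percentile 80.2. It was -0.03 without probe sets that can match several transcripts. With members matched through synonyms as well, 24 genes had a median of 0.08, at percentile 92.9. The most distant were DMAP1 at -0.60 and ING3 at -0.34 on one side and YEATS4 at 0.39 and the H2A.Z chaperone ANP32E at 0.33 on the other, the last with probe sets from -0.29 to 0.94. VPS72, which binds H2A.Z in the SRCAP and TIP60 complexes, stood at 0.22, TRRAP at 0.22, BRD8 at 0.29, EPC2 at 0.28 and INO80C at 0.24. ACTR6 (0.13), MEAF6 (0.13), RUVBL1 (0.03), MCRS1 (0.03), ACTR8 (0.00), ACTL6A (-0.01), KAT5 (-0.01), MRGBP (-0.03), EPC1 (-0.05), INO80 (-0.11), UCHL5 (-0.13) and ACTR5 (-0.18) differed less.

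Clones of a cell line can differ in chromosome number, so genes were also grouped by chromosome. Over 29 chromosomes with at least 30 measured genes the medians ran only from -0.12 to 0.02, around a median of -0.06 over all genes. No chromosome median differed 1.5-fold from it, so no chromosome shifted as a whole by that much. Of these 29 chromosomes, 5 lay outside the central 95% of random sets, where 1.45 would if genes of a chromosome varied independently. Chromosome 2 (-0.10) and chromosome Z (-0.11) were on the low side, and chromosomes 19 (0.01), 20 (0.01) and 23 (0.02) on the high side. The sign of the last 3 changed with the floor at the 40th percentile, where the median over all genes was -0.11.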

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

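The array also carries 57 probe sets for vector and reporter sequences, which the comparisons above do not use. The tests in this part were chosen after the signals were seen. Of these, 4 were above the floor on the H2A.Z-1 KO array and under it on the H2A.Z-2 KO array, with signals of 23183, 10950, 486.7 and 374.9. By their names, the probe sets with signals of 486.7 and 374.9 were made for the same sequence. A further 2 were above the floor only on the H2A.Z-2 KO array, with signals of 210.4 and 140.6.

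Of all 57 vector probe sets, 7.02% were above the floor on the H2A.Z-1 KO array and 3.51% on the H2A.Z-2 KO array, against 38.6% of the other probe sets on the H2A.Z-1 KO array. This does not exclude non-specific hybridisation to vector probe sets, since single probe sets can match an unrelated transcript. A first test looked only at the other 53 probe sets, of which 0 were above the floor, and was dropped because the choice of the 4 fixed that outcome. The bound for a negative result was lowered from 10% to 1% at the same time, after the signals were seen. The reason was that a low share over all probe sets does not exclude a match of a few. The share of 7.02% would have met the first bound. The chosen 4 probe sets alone put the share above 1%, so the new bound could not be met. The share therefore decides nothing. This line is described as carrying an introduced H2A.Z-1 transgene under tetracycline control, so vector sequence carried by the conditional H2A.Z-1 KO line is a candidate explanation for the 4 probe sets. Both stay open, because neither plasmid nor probe sequences were used here.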

How the results depend on the processing

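No paired analysis was possible because each genotype has 1 array, and no array could be left out. One alternative, matching list members through synonyms, was chosen after seeing the data; it left 8 lists above and 3 below the central 95% of random lists. All 34 leading genes kept their sign under each alternative that measured them, but 7 of them fell under 2-fold in 1 setting each: MLIP (-0.45) without probe sets matching several transcripts, SFRP1 (0.93) and RRBP1 (-0.96) with no floor, and AHR1A (-0.95), PLS3 (-0.43), BEND7 (-0.94) and GPR65 (-0.58) with the floor at the 80th percentile. Of the 34, 5 had no value without probe sets matching several transcripts: H2AFZ, BTLA, LGALS1A, CD83 and CD200R1A. The B-cell receptor, G1/S, G2/M and unfolded protein lists stayed outside the central 95% in the same direction under each alternative. Signals under the floor have no order, so counts and folds of dim genes move with it. Probe sets at least 2-fold higher on the H2A.Z-1 KO and H2A.Z-2 KO arrays numbered 967 and 1913 with the floor at the 40th percentile, 219 and 155 at the 80th, 4080 and 7338 with no floor, 214 and 241 at 3-fold, and 1487 and 2087 at 1.5-fold. For genes they were 133 and 92 with the floor at the 80th percentile, 905 and 1970 with no floor, 91 and 111 at 3-fold, and 603 and 929 at 1.5-fold, and 312 and 641 with the floor at the 40th percentile. These follow from the floor and threshold themselves. The log2 ratio of H2AZ2, a bound set by the floor, was 8.95 and 5.20 with the floor at the 40th and 80th percentiles, 8.92 with no floor and 8.19 without probe sets matching several transcripts, against 7.73. Lists above the central 95% numbered 5 with list means and lists below it 6 with the floor at the 80th percentile. Chromosomes above it numbered 1 with quantile normalization, 1 with the floor at the 80th percentile and 1 with no floor, and chromosomes below it 4 with the floor at the 40th percentile and 1 without probe sets matching several transcripts. With the floor at the 40th percentile the medians of chromosomes 19, 20 and 23 turned to -0.0307, -0.0760 and -0.0549, with no floor to -0.0301, -0.141 and -0.131, and without probe sets matching several transcripts that of chromosome 23 to -0.0411. The cause of these list and chromosome changes was not tested. The median log2 ratio of all genes was -0.06 as deposited and -0.16 with no floor.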

Other observations

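The tests on endoplasmic reticulum membrane genes, BCL6-repressed genes, brightness, markers of other cells, and gene families among neighbours were chosen after related results were seen; the tests on transport and neighbouring genes were set before theirs. The further genes named here were picked after their values were seen. Of 7 measured Wnt antagonists or feedback genes, 4 were at least 2-fold higher in H2A.Z-1 KO cells: SFRP2 at least 11.8-fold and DKK3 9.70-fold, beside SFRP1 and DACT2. Because the Wnt list was built round these genes, its median of 3.28 over 7 measured members (percentile 100), or 0.24 over 11 with the floor at the 40th percentile (98.7) and 0.09 over 17 with no floor (94.1), is no independent evidence, and the members not seen beforehand, DACT1, ZNRF3 and FRZB, stood at -0.07, 0.08 and 0.88. RAC2 was 9.14-fold and its inhibitor gene ARHGDIB 4.51-fold higher in H2A.Z-1 KO cells, in the same direction as PREX1, whereas ITGA4 and CDH11 were higher in H2A.Z-2 KO cells; the adhesion and migration list as a whole lay inside the central 95%, at percentile 6.41, but outside it with the floor at the 80th percentile (-0.52, percentile 0). BCL11A, a transcription factor of early B cells, was at least 8.23-fold higher in H2A.Z-1 KO cells over 4 probe sets that ranged from 0.31 to 5.25. TIPARP, a target gene of the aryl hydrocarbon receptor, was 7.89-fold higher in H2A.Z-2 KO cells, as AHR1A was. Of 10 chicken Ig-like receptor genes listed, 3 were measured, with a median of -1.73, too few to describe as a list.

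Higher B-cell receptor, replication and mitosis genes on the H2A.Z-1 KO array went together with higher secretion and unfolded protein genes on the H2A.Z-2 KO array, 5 lists chosen for this pattern after their shifts were seen. After the brightness trend was removed each list kept at least 89.2% of its distance from the median of all genes, while the share of 2-fold probe sets higher on the H2A.Z-1 KO array moved from 45.0% to 54.8%, which argues against that trend as the whole cause. This replaced a test set beforehand on percentiles, which all 5 lists had passed but which random lists of the same brightness largely decide in advance. A single scaling factor moves all lists alike, so it cannot make these lists differ from each other. With the median log2 ratio set to 0, the B-cell receptor list stood at 0.50 and the secretion list at -0.19. Among 24 measured markers of T, myeloid, erythroid and fibroblast cells, 2 were at least 2-fold higher on the H2A.Z-2 KO array, the brightest being CD5 at 540.3. Without probe sets matching several transcripts they were 3 of 25, with the same brightest marker. On the H2A.Z-1 KO array 1 T or NK cell marker and 2 myeloid markers passed 2-fold, and admixture into that culture was not tested. The low signals on the H2A.Z-2 KO array argue against admixture of those cells into the H2A.Z-2 KO culture as the whole cause. A share of 26.4% would be needed to lower B-cell transcripts by the median of the B-cell receptor list. This test replaced an earlier one, on the spread of the B-cell receptor genes' ratios, after that result was seen; it had pointed the same way. Whether the pattern follows from the knocked-out variant, from permanent against tetracycline-controlled loss, or from a difference between clones cannot be told apart. Each genotype has 1 array, and the way of loss differs together with the genotype.

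A broader secretory programme in H2A.Z-2 KO cells, one hypothesis for the lower group, predicted that genes of transport from the endoplasmic reticulum to the Golgi would shift too. Their median over 49 genes was -0.15, at percentile 1.59, with TMED3 3.83-fold higher on the H2A.Z-2 KO array; the list was outside the central 95% under 5 of 9 alternatives but inside it with quantile normalization (3.58), the brightness trend removed (4.98), no floor (4.63) and without probe sets matching several transcripts (4.80), so the bound set beforehand was met in the main analysis, but the support depends on the processing. Genes of the endoplasmic reticulum membrane and N-glycosylation had a median of -0.33 over 39 genes, at percentile 0. Without members already seen, 33 genes had a median of -0.24, at percentile 0.29, or 3.86 with the mean.

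A second hypothesis was that genes repressed by BCL6, listed from general knowledge, are lower where BCL6 is higher. Of 13 measured genes 3 were at least 2-fold higher on the H2A.Z-2 KO array, led by GPR183 (at least 5.88-fold) and ID2, and none on the other. The median of -0.11 lay at percentile 36.5, well inside the range of random lists. Only the mean, 1 of 9 alternatives, left the central range, at percentile 0.55. The other alternatives lay between 14.2, with quantile normalization, and 45.1, with the brightest probe set per gene. The median thus gave no support to the hypothesis, but decides nothing because members went both ways. The bound for a negative result was first set at the 10th percentile, which the median at percentile 36.5 would have met. It was replaced for that reason after the value was seen.

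Genes that differed 2-fold were neighbours in the order of measured genes more often than random placement gave. Neighbours here are consecutive measured genes on a chromosome. Unmeasured genes can lie between them, and distance was not used. Among 7975 genes in chromosome order, 36 neighbouring pairs differed at least 2-fold in the same direction. This was at percentile 99.995 of random placements, whose median was 18 and whose central 95% ended at 26.0. Without neighbours whose symbols share their first 3 letters, 31 pairs remained, at percentile 99.88, which argues against signal shared between copies of 1 gene family as the whole cause; families whose symbols differ were not covered. One pair is H2AFZ itself with PPP3CA, the next measured gene. PPP3CA was 3.59-fold higher on the H2A.Z-2 KO array with 5 probe sets from -2.24 to -1.29. Other pairs are VPREB3 with VPS29L, VAT1 with IFI35 and GPR65 with KCNK10. Runs of genes that change together may explain the excess, and whether they mark shared regulation, the targeted locus or differences between clones was not tested.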
